A study of Mus musculus with 30 samples.

How the data were processed

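RNA from fresh-frozen liver outside tumours was measured on Affymetrix HT MG-430 PM one-colour arrays, 1 array per mouse, for 30 mice. Per the labels' protocols, total RNA came from 20 mg of tissue and was extracted with Trizol and purified on RNeasy columns. The deposited values are intensity per probe set, and the authors made them with RMA and quantile normalization between arrays in the GenePattern module ExpressionFileCreator, per the series design text and the submitters' processing notes. The version of RMA is not given in the sources used here. All deposited intensity values are positive and on a linear scale, so log2 was taken here before any other step. The minimum intensity lay between 13.8 and 14.8 in every array and the maximum between 10970 and 13668, so small fold changes near the lower end are compressed by background signal. The number of arrays limits the precision.

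The array table holds 45141 probe sets, of which 104 are controls. The deposited annotation gives 1 gene symbol for 28898 probe sets, several for 551 and none for 15588. Symbols of 28689 probe sets matched the mouse RefSeq table (assembly GRCm38.p6) through their Entrez identifiers, and 209 identifiers were not in that table. The table was used only for names and for which genes neighbour each other. For each of 17097 genes the probe set with the highest mean over all 30 arrays was used. A total of 7180 of these genes have several probe sets. No gene was removed for low intensity. Ptgs1, a target of both aspirin and sulindac, is not named on any probe set with 1 symbol and has no value here.

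Mice were grouped by the labels into healthy on chow (5), vehicle on CD-HFD without HCC (5), vehicle on CD-HFD with HCC and fibrosis (4), sulindac on CD-HFD (10) and aspirin with clopidogrel on CD-HFD (6). The series design text lists 4 vehicle mice while the labels give 9, and the labels were followed. Mice are named as in their titles, with Hlth for healthy, Veh_low and Veh_high for vehicle without and with HCC, Sulin for sulindac and AspClo for aspirin with clopidogrel, each followed by the animal number. The labels give no sex, batch or collection time.

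A linear model with 5 group means was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, leaving 25 residual degrees of freedom and 2.37 prior degrees of freedom. The vehicle mean was taken over its 9 mice. Moderated tests were adjusted by the Benjamini-Hochberg method over the 17097 genes within each comparison, and an adjusted p under 0.05 was the threshold. The 5 main comparisons were vehicle against healthy, vehicle with HCC against vehicle without HCC, each drug arm against vehicle, and the drug arms against each other. The secondary comparisons set each vehicle group against healthy. With equal spread and no change, 855 of 17097 genes have an unadjusted p under 0.05.

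Gene lists for 40 pathways, cell types and tissues were written from general knowledge, and the 39 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 39 lists. Each list was also tested with the correlation estimated from the data, with fry, and with a two-sided exact permutation of mice on the mean log2 of its members. The preset correlation treats members as nearly independent, and the estimated one does not. A list score is a mouse's mean log2 over the members relative to the healthy mean. Counts adjusted over the list alone apply the Benjamini-Hochberg method within that list.

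Genes are named by rule. In each main comparison these are up to 10 genes that rose and 10 that fell with the largest change among those past the threshold, with the brighter group at or above the median gene mean of 4.90 (log2) and without uninformative symbols. The rule adds up to 4 members with the smallest p past the threshold from each list that passed, or that had at least 5 members past it, and the drug targets Ptgs2 and P2ry12. Genes outside the rule are said to be chosen after their values were seen. The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

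Return toward healthy was measured across genes as the correlation of the diet effect with the drug effect, with the vehicle mice divided so that no array entered both effects (100 seeded splits). A negative value means movement toward healthy and a positive value means movement further in the direction of the diet. Genes are not independent replicates, so no p is given. Simulations of unchanged groups (50) gave the value that shared vehicle arrays alone produce.

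Simulated arrays had the spread of the real genes and 200 changed genes among 17097, drawn from those at or above the median gene mean. The fit was tested on them over 5 simulations. At a log2 change of 1 it recovered 92.8% of changed genes for the diet, 86.4% for HCC, 97.2% for sulindac, 93.2% for aspirin with clopidogrel and 92.4% for the drug arms against each other. At a log2 change of 0.5 it recovered 65.6%, 54.4%, 82.0%, 68.4% and 72.4% in that order. The share of false calls among the simulated calls was 6.0%, 5.8%, 5.2%, 4.7% and 5.2%. Simulated values were independent draws from a normal distribution. Recovery and false calls may therefore differ for dim genes, for arrays that vary together and for a group of unlike mice.

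Alternatives changed the filter on dim genes, the gene summary, the normalization, the variance prior, array weights, the samples in the fit, the threshold, the vehicle reference and the list test, and left out each mouse in turn. Alternatives added after the data were seen left out aspirin and clopidogrel mice with high Xist (log2 above 8), used high Xist as a covariate, or left out healthy and vehicle arrays that lay nearer the other group. For the last, each array's deviation from the midpoint of the group means, computed without it, was correlated with the difference between those means. This used only the brighter genes, those at or above the median gene mean of 4.90. Where mice were left out, lists were tested with camera at the preset correlation only. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.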

Results

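Liver gene expression was measured in 30 mice, 1 array each. Healthy livers came from 5 mice on chow. The other mice received CD-HFD, a choline-deficient high-fat diet that induces steatohepatitis and hepatocellular carcinoma (HCC). On this diet, 9 mice received vehicle, 5 without HCC and 4 with HCC and fibrosis, 10 received sulindac, a cyclooxygenase inhibitor, and 6 received aspirin with clopidogrel, which blocks the platelet receptor P2Y12. Median intensity per array lay between 24.1 and 24.6, and correlations between pairs of arrays across probe sets lay between 0.974 and 0.996.

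The diet comparison asked which genes differ between vehicle livers on CD-HFD and healthy livers. Kitl, which encodes stem cell factor, averaged 5.97 ± 0.34 (SD, n = 5, log2 intensity) in healthy livers and 5.31 ± 0.26 (n = 9) in vehicle livers, a change of -0.66 (SE 0.095, adjusted p = 0.00272). Lad1, which encodes an anchoring filament protein, averaged 5.36 ± 0.17 (n = 5) in healthy and 4.78 ± 0.22 (n = 9) in vehicle livers, a change of -0.58 (SE 0.098, adjusted p = 0.0226). Of the 33 type I interferon response genes, 29 were higher in vehicle livers, with a median log2 change of 0.275 and camera adjusted p = 4.19e-08 (adjusted p = 0.596 with an estimated correlation). The interferon score per mouse ranged from -0.32 to 0.69 in healthy livers and from -0.23 to 0.72 in vehicle livers. The overlap rested on Hlth_1798 (0.69), Hlth_1807 (0.013), Veh_low_794 (-0.14) and Veh_low_1819 (-0.23), which lay nearer the other group over the brighter genes. The other healthy mice had scores of at most -0.15 and the other vehicle mice of at least 0.29. The mean change of the list was 0.314 with these 4 arrays and 0.692 without them.

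Antigen presentation genes had a median change of 0.233 (30 of 34 members higher, adjusted p = 5.44e-07) and lipid droplet genes one of 0.16 (21 of 24 higher, adjusted p = 2.53e-05). Both had adjusted p = 0.596 with an estimated correlation. Acute phase genes (median 0.092, adjusted p = 0.00701), stellate cell genes (0.103, adjusted p = 0.00967), endothelial genes (0.086, adjusted p = 0.00967), adipose genes (0.149, adjusted p = 0.0191) and p53 targets (0.079, adjusted p = 0.0447) were also higher as lists. Male-biased liver genes (median -0.285, adjusted p = 0.00967), cholangiocyte genes (-0.107, adjusted p = 0.00967) and targets of the aryl hydrocarbon receptor (-0.061, adjusted p = 0.0191) were lower as lists. With an estimated correlation these 8 lists had adjusted p between 0.596 and 0.655, and no list passed the exact permutation of mice. No list member passed over all genes tested. Adjusted over the list alone, 3 antigen presentation genes and 1 gene each of the lipid droplet, acute phase, stellate and endothelial lists were higher, and 2 aryl hydrocarbon receptor targets were lower. The acute phase list lost its call without Hlth_1804 or Hlth_1965 (highest adjusted p = 0.121), the stellate list without Hlth_1804 (0.0609), and the male-biased list without either or Hlth_1968 (0.125). The endothelial and cholangiocyte lists lost it without Hlth_1807 (adjusted p = 0.0755 and 0.778), the adipose list without Veh_low_794 (0.148) and the aryl hydrocarbon receptor list without Hlth_1798, Hlth_1807 or Veh_low_1819 (0.134). The p53 list lost it without Hlth_1804, Hlth_1965, Hlth_1968, Veh_high_1770, Veh_low_1810 or Veh_low_1825 (highest adjusted p = 0.234).

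Without Hlth_1798, Hlth_1807, Veh_low_794 and Veh_low_1819, which were selected on the measured values, the mean change went from 0.276 to 0.621 for antigen presentation genes (adjusted p = 3.12e-13), from 0.339 to 0.746 for lipid droplet genes (7.74e-11), from 0.179 to 0.592 for acute phase genes (3.13e-08), from 0.172 to 0.296 for stellate cell genes (0.000676) and from 0.067 to 0.206 for p53 targets (0.0019). It went from -0.493 to -1.25 for male-biased genes (adjusted p = 2.13e-07). The endothelial, adipose and aryl hydrocarbon receptor lists lost their calls there, with mean changes of 0.109 (adjusted p = 0.203), 0.311 (0.191) and -0.035 (0.707), and the cholangiocyte list went from -0.142 to 0.047 (0.38). The fibrosis list had a median of 0.026 (adjusted p = 0.714) with all arrays and the T and NK cell list one of 0.023 (adjusted p = 0.137). The estimated correlation passed no diet list with all arrays and was not applied without the 4. Without these 4 arrays 12 lists passed at the preset correlation that had not passed with all arrays. The mean went from 0.027 to 0.549 for fibrosis genes (adjusted p = 1.28e-14), from 0.174 to 0.879 for macrophage genes (2.17e-17), from 0.146 to 0.799 for lipid-associated macrophage genes (2.79e-12), from 0.02 to 0.72 for oncofetal genes (0.000212) and from 0.026 to 0.224 for chemokines (0.00165). It became 0.189 for TGF-beta genes (adjusted p = 0.00134), 0.292 for NRF2 targets (0.0055), 0.665 for female-biased genes (0.0159), 0.109 for T and NK cell genes (0.0493), -0.148 for hepatocyte genes (0.000134), -0.068 for targets of CAR and PXR (0.00939) and -0.27 for cholesterol synthesis genes (0.0222). Fibrosis scores were 1.04 in Hlth_1807 and 0.30 in Hlth_1798, between -0.52 and -0.38 in the other healthy mice and between -0.12 and 0.30 in the other 7 vehicle mice. Oncofetal scores were 0.85 in Hlth_1807 and in Hlth_1798 and between -0.64 and -0.45 in the other healthy mice.

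In all, 2 of 17097 genes passed for the diet, both lower in vehicle livers, and 1151 had an unadjusted p under 0.05. With only the groups compared in the fit, limma gave 0 genes, and 917 had an unadjusted p under 0.05. The count was 36 without healthy mouse Hlth_1798, 11 without healthy mouse Hlth_1807, 6 without vehicle mouse Veh_high_1831 and 4 without vehicle mouse Veh_low_1819. It was 1 without healthy mouse Hlth_1968 or any of vehicle mice Veh_high_2088, Veh_low_2091 and Veh_low_794, each of which ended the call of Lad1, as did leaving out healthy mouse Hlth_1804 (adjusted p = 0.0983). A total of 4 arrays, healthy Hlth_1798 and Hlth_1807 and vehicle Veh_low_794 and Veh_low_1819, lay nearer the other group, and 959 genes passed without them. Against healthy livers, limma gave 0 genes for vehicle without HCC (909 at an unadjusted p under 0.05) and 17 for vehicle with HCC (5 higher, 12 lower), Kitl among the latter. The count of 17 was 110 without healthy mouse Hlth_1798, 106 without Hlth_1807, 3 without Hlth_1804 or Hlth_1965, and 1 without Hlth_1968. It was 9 without vehicle mouse Veh_high_1770 and 1 without Veh_high_2088, while without Hlth_1798, Hlth_1807 or Veh_low_1810 the count of 0 became 1.

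**Figure D1:**
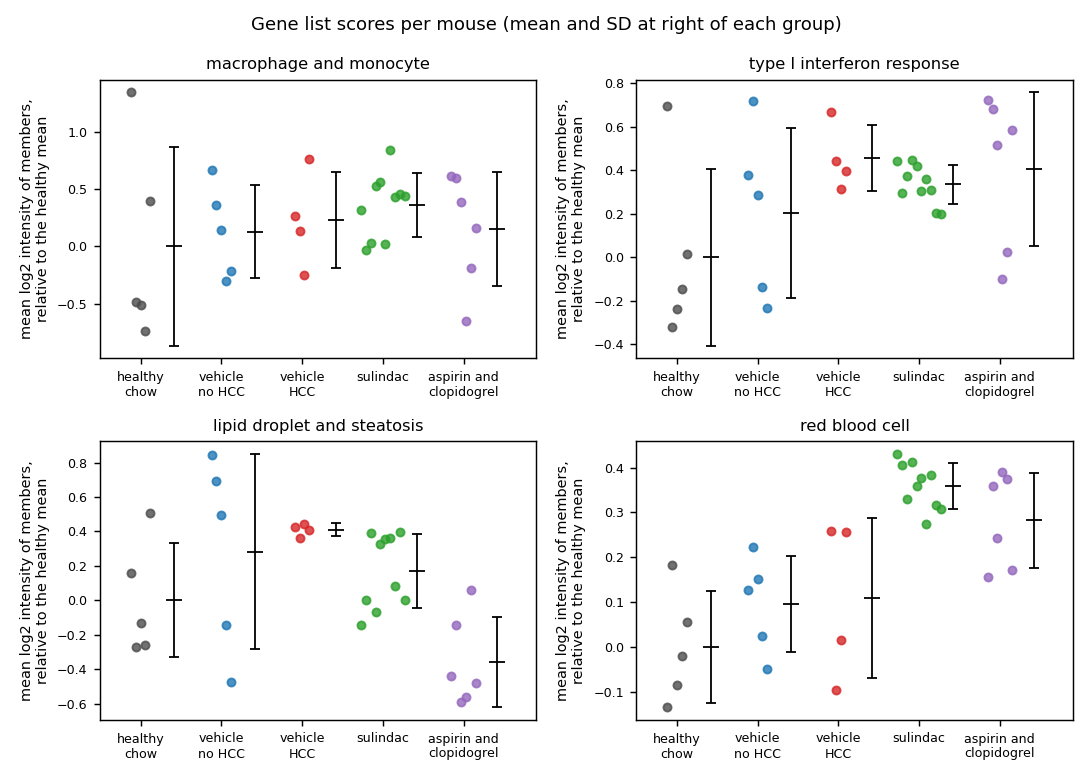
List scores (mean log2 over members relative to the healthy mean) per mouse in the 5 groups for macrophage, type I interferon, lipid droplet and red blood cell genes, with points for mice and black marks and bars for mean ± SD. Red blood cell scores averaged 0.36 ± 0.052 under sulindac and 0.102 ± 0.133 in all vehicle mice, and lipid droplet scores averaged -0.36 ± 0.261 under aspirin with clopidogrel.

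The HCC comparison asked how liver outside the tumour differs between vehicle mice with HCC and vehicle mice without it. Id1, a transcriptional target of BMP signalling, averaged 8.95 ± 0.69 (SD, n = 5) without HCC and 6.29 ± 0.35 (n = 4) with HCC, and 7.28 ± 0.67 (n = 5) in healthy livers. Its change was -2.66 (SE 0.479, adjusted p = 0.019). Id3 fell with it, by 1.27 on the log2 scale (SE 0.234, adjusted p = 0.0195), from a mean of 10.53 ± 0.52 to 9.26 ± 0.39. The clock repressor Cry1 averaged 8.23 ± 0.75 without HCC, 6.04 ± 0.62 with HCC and 8.31 ± 0.16 in healthy livers, a change of -2.18 (SE 0.38, adjusted p = 0.019). The ubiquitin ligase gene Lonrf3 fell by 1.42 (SE 0.226, adjusted p = 0.0136), and Fam114a1 rose by 1.09 (SE 0.21, adjusted p = 0.0334), the only gene that rose.

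The nuclear pore gene Ahctf1 fell by 0.99, and Fam13b, Wrnip1, Ncbp2, Rest and Smarca5 fell by 0.77, 0.75, 0.50, 0.45 and 0.41, with adjusted p between 0.0136 and 0.0343. Only 2 of 4 probe sets of Rest had this direction. The cap-binding gene Ncbp2 and the chromatin remodeller gene Smarca5 had it in 3 of 3 probe sets each. Cholesterol synthesis genes were higher with HCC, 19 of 20 members with a median of 0.674 (adjusted p = 3.14e-10), but with an estimated correlation the list had adjusted p = 0.853, and no member passed over all genes. The exact permutation p of that list was 0.0476 and its adjusted value 0.649, with 0.00794 the smallest p the design allows. De novo lipogenesis genes had a median of 0.611 (adjusted p = 0.000177), antigen presentation genes 0.234 (adjusted p = 1.79e-06) and type I interferon genes 0.164 (adjusted p = 7.69e-05). Fibrosis genes had a median of 0.09 (36 of 46 members higher, adjusted p = 0.0466), and acute phase genes one of 0.072 (adjusted p = 0.0469). Targets of PPAR-alpha had a median of -0.102 (adjusted p = 8.83e-05), resident Kupffer cell genes, Id3 among them, one of -0.514 (adjusted p = 0.01), and endothelial genes one of -0.104 (adjusted p = 0.035). The other 8 lists also had adjusted p = 0.853 with an estimated correlation. Adjusted over the list alone, 4 cholesterol synthesis genes were higher, and 3 PPAR-alpha targets, 2 Kupffer cell genes, 1 acute phase gene and 1 endothelial gene were lower. Over all genes tested, Id3 was the only member that passed. The Kupffer cell list lost its call without Veh_high_1770, Veh_high_1831 or Veh_low_1810 (highest adjusted p = 0.189) and the endothelial list without Veh_high_1831, Veh_low_1825 or Veh_low_2091 (0.512). The fibrosis list lost it without Veh_high_1770, Veh_low_2091, Veh_low_794 or Veh_low_1819 (0.572), and the acute phase list without Veh_high_798, Veh_high_1770, Veh_high_1831, Veh_low_1825, Veh_low_794 or Veh_low_1819 (0.252). Without both Veh_low_794 and Veh_low_1819 the interferon list had a mean change of -0.0059 (adjusted p = 0.949), the lipogenesis list one of 0.24 (0.108), the fibrosis list one of 0.017 (0.756) and the acute phase list one of -0.011 (0.803). The antigen presentation list went from a mean of 0.294 to 0.141 (adjusted p = 0.0072) and the PPAR-alpha list from -0.305 to -0.475 (5.94e-13), and both kept their calls. Another 4 lists, which had not passed with all mice, passed there at the preset correlation, the only one applied. Their means were 0.172 for ER stress genes (adjusted p = 0.000399), -0.226 for p53 targets (0.00412), -0.267 for lipid droplet genes (0.00559) and -0.216 for targets of CAR and PXR (0.0072). Veh_low_794 and Veh_low_1819 were selected on the measured values for lying nearer healthy, so list changes without them follow in part from the selection.

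In all, 15 genes passed, 1 higher and 14 lower with HCC, and 1517 had an unadjusted p under 0.05. With only the 2 vehicle groups in the fit, limma gave 0 genes, and 1536 had an unadjusted p under 0.05. In the fit of all groups the count was 0 without vehicle mouse Veh_high_2088, when Id1 and Lonrf3 had adjusted p = 0.116 and Fam13b 0.301, and 1 without Veh_high_1831. It was 2 without Veh_low_2091, 4 without Veh_low_794 or Veh_low_1819, and 33 without Veh_high_798. None of the 11 named genes that passed kept its call without Veh_high_2088 or Veh_high_1831. In these mice the clock output gene Dbp, chosen after its values were seen, was at 10.20 and 10.00, against 4.60 in Veh_high_798, 4.37 in Veh_high_1770 and between 4.40 and 5.20 in the mice without HCC. Cry1 was at 5.55 and 5.51 in Veh_high_2088 and Veh_high_1831 and at 6.76 and 6.35 in Veh_high_798 and Veh_high_1770, with a lowest value of 7.12 without HCC.

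**Figure D2:**
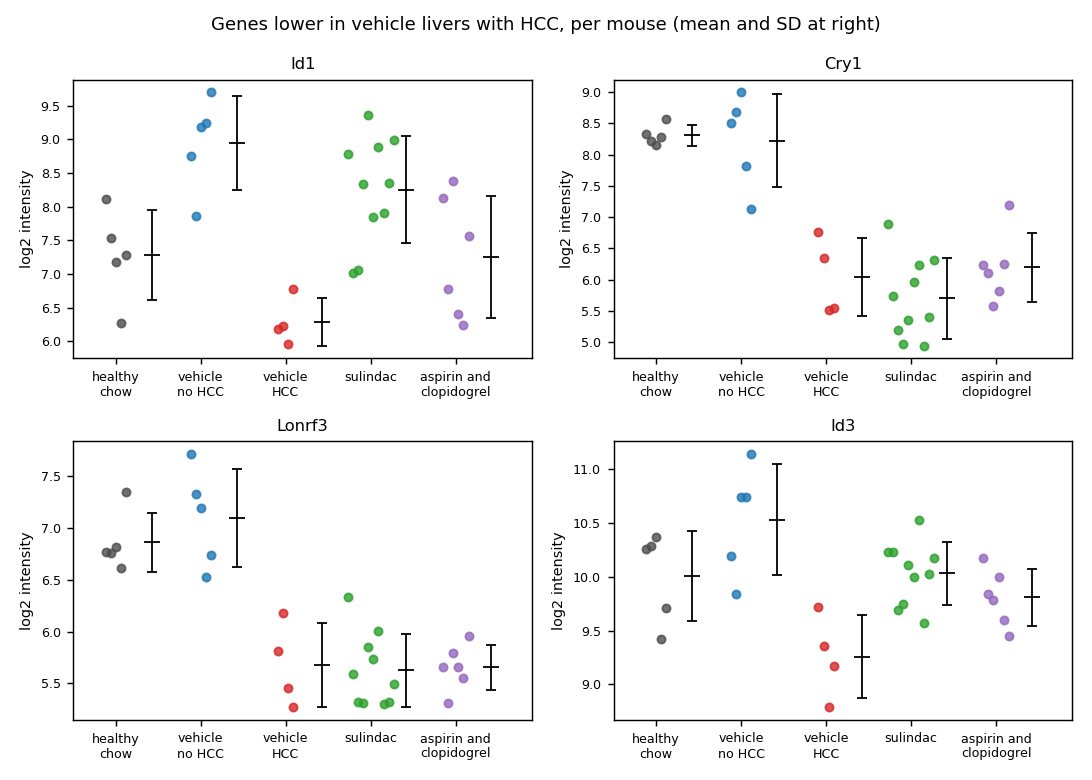
Log2 intensity of Id1, Cry1, Lonrf3 and Id3 per mouse in the 5 groups, with points for mice and black marks and bars for mean ± SD. Cry1 and Lonrf3 averaged 6.04 and 5.68 in vehicle livers with HCC and 5.70 and 5.63 under sulindac, below the healthy means of 8.31 and 6.86.

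The sulindac comparison asked what the drug, given during the diet, changed relative to vehicle. Wdfy1, which encodes an endosomal adaptor, averaged 5.19 ± 0.26 (SD, n = 9) under vehicle, 7.69 ± 0.16 (n = 10) under sulindac and 5.05 ± 0.18 (n = 5) in healthy livers, a change of 2.50 (SE 0.227, adjusted p = 2.58e-07). The mitochondrial transhydrogenase gene Nnt rose by 0.97 (SE 0.13, adjusted p = 0.000145) and Plekhj1 by 0.71 (SE 0.087, adjusted p = 4.68e-05). The mitochondrial iron carrier gene Slc25a37 fell by 0.92 (SE 0.107, adjusted p = 2.51e-05, 2 of 3 probe sets in this direction) and Entpd4 by 0.74 (SE 0.097, adjusted p = 0.000124, 1 of 2 probe sets). All 10 sulindac mice lay outside the range of the 14 healthy and vehicle mice for these 5 genes.

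The haemoglobin genes Hba-a1 and Hbb-b2 rose by 1.08 (SE 0.187, adjusted p = 0.00469) and 1.09 (SE 0.2, adjusted p = 0.00909). Hba-a1 averaged 12.62 ± 0.13 (n = 10) under sulindac, 11.54 ± 0.63 (n = 9) under vehicle and 10.87 ± 0.57 (n = 5) in healthy livers. Red blood cell genes as a list had a median of 0.052 and a mean of 0.258 (6 of 9 members higher, adjusted p = 0.00656), with adjusted p = 0.0614 with an estimated correlation. The list's exact permutation p was 1.08e-05, the smallest the permutations can give (adjusted p = 0.000421), with 2 members past the test over all genes and 3 adjusted over the list alone. The stress gene Gadd45a rose by 1.01 (SE 0.208, adjusted p = 0.0302), from 5.93 ± 0.36 to 6.93 ± 0.55. Cry1 fell by 1.56 (SE 0.26, adjusted p = 0.00407) to 5.70 ± 0.64 and Lonrf3 by 0.84 (SE 0.155, adjusted p = 0.00909), the direction both had with HCC. A score of day minus night clock genes without Cry1, chosen after the values were seen, did not pass after adjustment (exact permutation p = 0.0238, adjusted p = 0.0952 over 4 comparisons). Srp54c, Nat9, Shoc2 and Nsmce1 rose by between 0.43 and 0.49, and Fam25c, Celsr1, Cmtm4, Paip1, Sfi1 and Ankrd13a fell by between 0.42 and 0.82, with adjusted p between 0.00113 and 0.035.

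Acute phase genes (median 0.108, adjusted p = 0.00656), endothelial genes (0.159, adjusted p = 0.00656), Kupffer cell genes (0.221, adjusted p = 0.039) and cell cycle genes (0.051, adjusted p = 0.039) were higher as lists under sulindac. Targets of the oxidative stress factor NRF2 (median -0.1, adjusted p = 0.00656) and adipose genes (-0.17, adjusted p = 0.0304) were lower. These 6 lists had adjusted p = 0.992 with an estimated correlation, and none had a member past the test over all genes. Adjusted over the list alone, 1 cell cycle gene was higher and 1 adipose gene lower. In all, 34 genes passed, 20 higher and 14 lower, and 1781 had an unadjusted p under 0.05. The count was 148 without vehicle mouse Veh_high_2088, 93 without Veh_high_1831, 21 without Veh_low_1825, 20 without Veh_low_2091 and 19 without Sulin_23. It was 168 against vehicle without HCC alone, 8 against vehicle with HCC alone and 143 without the 4 arrays nearer the other group. Of the 20 named genes that passed, 12 kept their call without any 1 mouse. Lonrf3 lost it without vehicle mouse Veh_low_1810, Veh_low_1825 or Veh_low_2091 (highest adjusted p = 0.0648), and Gadd45a without any of 9 mice (highest adjusted p = 0.0726, without Veh_low_1810). The acute phase and adipose lists lost their calls without vehicle mouse Veh_low_794 (adjusted p = 0.0543 and 0.157), and without the 4 arrays nearer the other group the acute phase list went from a mean of 0.162 to 0.027 (adjusted p = 0.331) and the cell cycle list from 0.075 to 0.043 (adjusted p = 0.595). Another 5 lists, which had not passed with them, passed without these arrays at the preset correlation. Their means were -0.355 for lipid droplet genes (adjusted p = 1.5e-07), -0.145 for PPAR-alpha targets (0.00334) and 0.455 for male-biased genes (0.00721). They were -0.123 for type I interferon genes (adjusted p = 0.00825) and -0.1 for p53 targets (0.022). The estimated correlation, which passed no sulindac list with all arrays, was not applied there. The arrays left out were selected on the measured values. Without the vehicle arrays among them the vehicle mean moves away from healthy, so falls of lists raised by the diet follow in part from the selection. Calls also ended for the endothelial list without Veh_high_1831 (0.155), and the Kupffer and cell cycle lists without any of 8 and 7 mice (highest adjusted p = 0.276 without Veh_high_1831 and 0.428 without Sulin_15). Celsr1, Cmtm4 and Nsmce1 lost theirs without Veh_low_2091 (adjusted p = 0.098, 0.0965 and 0.122) among others, Paip1 without Veh_low_1825 (0.0608), Sfi1 without Veh_low_1810 (0.0596) and Shoc2 without Veh_high_1770 (0.0581).

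**Figure D3:**
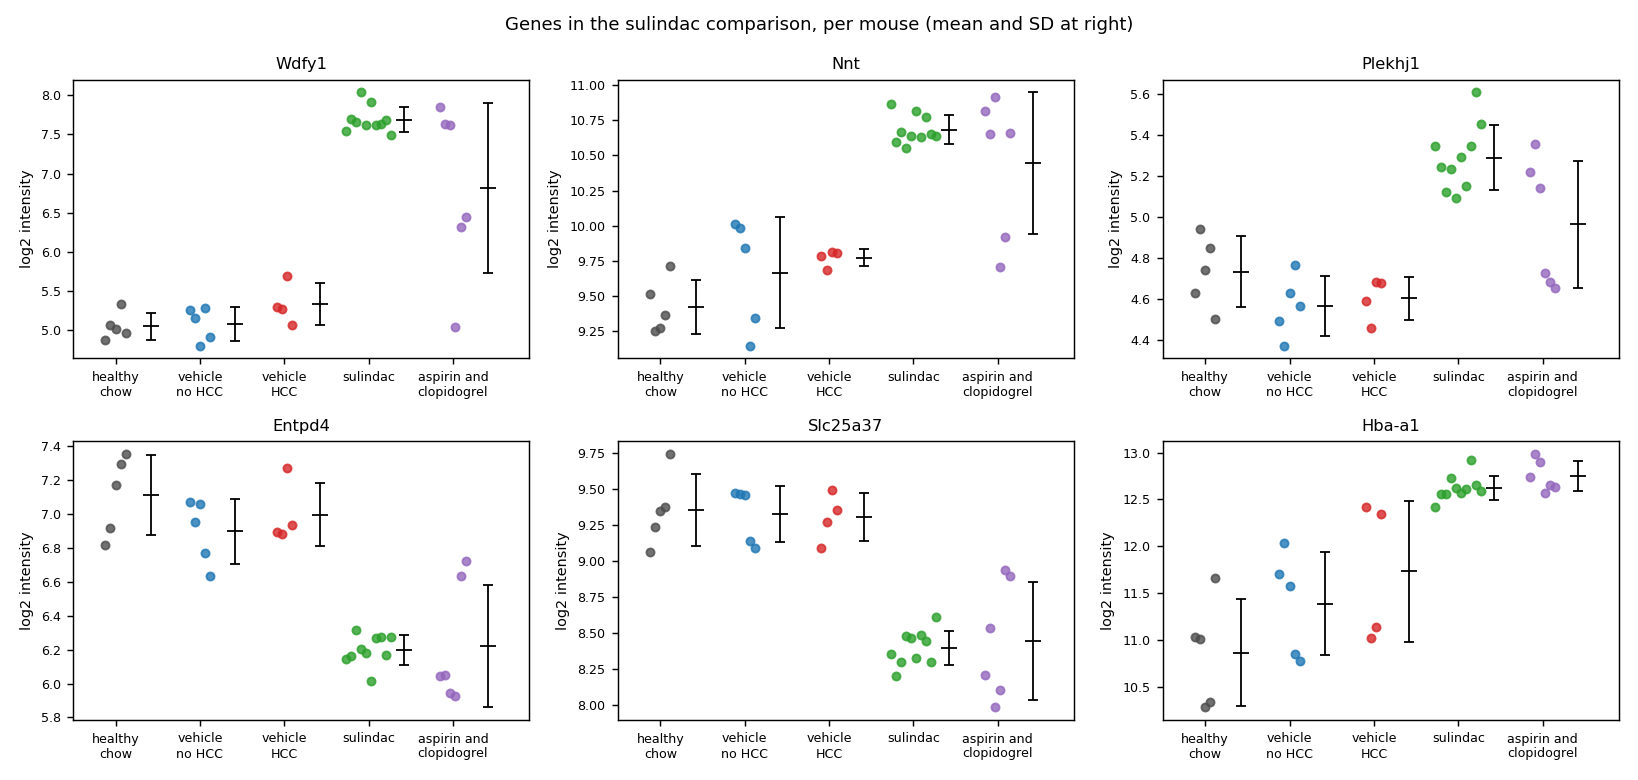
Log2 intensity of Wdfy1, Nnt, Plekhj1, Entpd4, Slc25a37 and Hba-a1 per mouse in the 5 groups, with points for mice and black marks and bars for mean ± SD. Wdfy1 lay between 7.50 and 8.04 in the 10 sulindac mice and between 4.80 and 5.70 in the 14 healthy and vehicle mice.

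The comparison of aspirin with clopidogrel against vehicle asked the same question for the other drug arm. Sult2a2, a sulfotransferase gene expressed mainly in female liver, averaged 4.45 ± 0.40 (SD, n = 9) under vehicle, 9.65 ± 4.06 (n = 6) under aspirin with clopidogrel and 4.42 ± 0.16 (n = 5) in healthy livers (change 5.20, SE 0.922, adjusted p = 0.00289). Xist, the RNA of the inactive X chromosome, rose by 4.21 (SE 0.745, adjusted p = 0.00289) and the Y-linked gene Eif2s3y fell by 2.55 (SE 0.52, adjusted p = 0.00877). Xist lay between 10.95 and 11.21 in AspClo_61, AspClo_64, AspClo_58 and AspClo_63 and at 4.80 and 4.56 in AspClo_60 and AspClo_62, and it was below 8 in all 24 mice of the other groups. Female-biased liver genes had a median of 1.67 (adjusted p = 6.76e-20, adjusted p = 0.0964 with an estimated correlation), with 12 of 18 members past the test over all genes and 16 adjusted over the list alone. Among them, Hao2 rose by 3.40 and Abcd2 by 1.68, and the cytochrome P450 genes Cyp3a41a, Cyp2b13 and Cyp3a16 rose by 3.99, 3.48 and 3.38.

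The transporter gene Slc22a26 rose by 3.91, Acot3 by 2.92, Nipal1 by 2.19 and Prom1 by 1.99. Male-biased liver genes had a median of -0.394 (adjusted p = 0.000321, adjusted p = 0.607 with an estimated correlation). Their mean change of -0.81 became -0.497 (adjusted p = 0.0614) without the 4 arrays nearer the other group and 0.444 (adjusted p = 0.359) without the 4 mice with high Xist. In that list Cyp4a12a fell by 3.32, Elovl3 by 2.42 and Cyp2d9 by 1.92, and 3 members passed both over all genes and adjusted over the list alone. The acetyltransferase genes Nat8 and Nat8f5 fell by 2.59 and 1.76. Adjusted p of the genes from Hao2 to Nat8f5 lay between 0.00109 and 0.0349. In the 2 mice with low Xist no gene of this and the preceding paragraph passed, and with 2 mice a lost call alone does not show that a gene follows sex. There the changes were 2.06 for Acot3, -1.03 for Nat8f5, 1.33 for Hao2, 0.80 for Abcd2, -0.57 for Cyp4a12a, -0.55 for Nat8, 0.50 for Slc22a26, -0.30 for Elovl3, 0.067 for Prom1 and 0.038 for Cyp2b13. Xist, Sult2a2, Cyp3a41a, Cyp3a16, Cyp3a44, Nipal1, Eif2s3y, Cyp2d9 and Alas2 changed sign there.

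**Figure D4:**
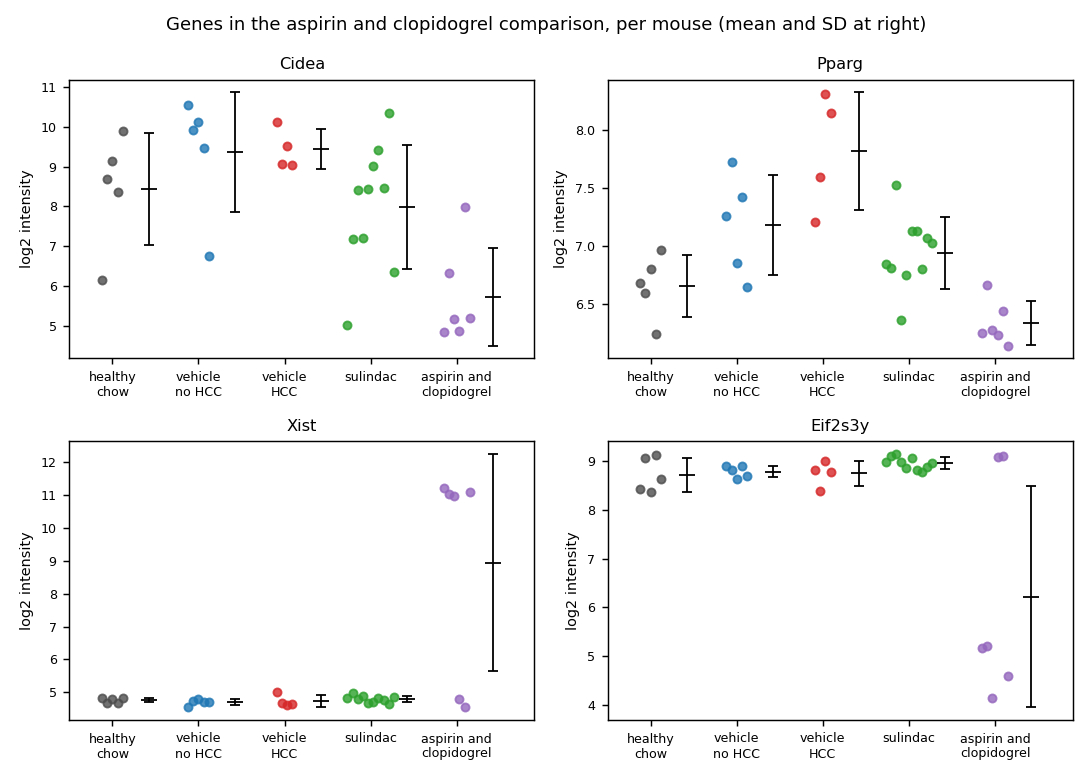
Log2 intensity of Cidea, Pparg, Xist and Eif2s3y per mouse in the 5 groups, with points for mice and black marks and bars for mean ± SD. Pparg lay between 6.14 and 6.66 in all 6 mice given aspirin with clopidogrel, while Xist was above 8 in 4 of them.

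Lipid droplet genes were lower under aspirin with clopidogrel. Cidea, which encodes a protein that enlarges lipid droplets, averaged 9.40 ± 1.11 (SD, n = 9) under vehicle, 5.73 ± 1.23 (n = 6) under the drugs and 8.45 ± 1.40 (n = 5) in healthy livers (change -3.67, SE 0.693, adjusted p = 0.00516). Pparg, the adipogenic nuclear receptor gene, fell by 1.13 (SE 0.171, adjusted p = 0.000924), from 7.46 ± 0.55 to 6.33 ± 0.19, against 6.65 ± 0.27 in healthy livers. Fitm1 fell by 1.70 (SE 0.215, adjusted p = 0.000213), Osbpl3 fell by 2.32 (SE 0.505, adjusted p = 0.0146) and the adhesion receptor gene Adgrv1 by 2.69 (SE 0.668, adjusted p = 0.0321), and Vldlr rose by 0.43 (SE 0.085, adjusted p = 0.00675). The list had a median of -0.325 (21 of 24 members lower, adjusted p = 8.49e-10), with adjusted p = 0.129 with an estimated correlation and an exact permutation p of 0.0048 (adjusted p = 0.0405). Over all genes 6 members passed lower and 1 higher, and adjusted over the list alone 11 lower and 1 higher. In the 2 mice with low Xist the changes of Cidea and Pparg were -2.97 and -1.12, with limma adjusted p of 0.45 and 0.129 at that group size. Cidea was at 4.86 in AspClo_60 and at 7.98 in AspClo_62, the latter inside the vehicle range of 6.77 to 10.55 only through Veh_low_1819, since the other 8 vehicle mice lay at 9.04 or above. Pparg was at 6.23 and 6.44 in these 2 mice, below the lowest vehicle mouse at 6.64.

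Targets of NRF2 had a median of -0.28 (25 of 28 members lower, adjusted p = 4.62e-09, adjusted p = 0.389 with an estimated correlation). Aox1 fell by 0.95 (adjusted p = 0.000771), Gstp1 by 0.45 (adjusted p = 0.00289), Ugdh by 0.46 (adjusted p = 0.0207) and Tkt by 0.33 (adjusted p = 0.0228). In the 2 mice with low Xist the changes were -0.37 for Aox1, -0.16 for Gstp1, -0.27 for Ugdh and -0.50 for Tkt, against -1.25, -0.59, -0.56 and -0.25 in the 4 with high Xist. In this list 5 members passed over all genes and 9 adjusted over the list alone. Haemoglobin genes rose as under sulindac, Hba-a1 by 1.21 (adjusted p = 0.00296) and Hbb-b2 by 1.14 (adjusted p = 0.00824), while the haem synthesis gene Alas2 fell by 1.11 (adjusted p = 0.0325). Red blood cell genes as a list had a median of 0.079 (adjusted p = 0.0405, adjusted p = 0.129 with an estimated correlation), with 2 higher and 1 lower over all genes and 3 higher and 1 lower adjusted over the list alone. The mean change of this list went from 0.181 to 0.281 (adjusted p = 0.0183) without the 4 mice with high Xist and to 0.149 (adjusted p = 0.056) without the 4 arrays nearer the other group.

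Targets of CAR and PXR had a median of 0.172 (adjusted p = 0.0423, adjusted p = 0.607 with an estimated correlation), with Cyp3a44 up by 0.98 and Aldh1a7 down (change -0.44, adjusted p = 0.000399). In that list 4 members were higher and 2 lower over all genes, and 8 higher and 3 lower adjusted over the list alone. Hepatocyte genes had a median of 0.062 (adjusted p = 8.36e-05, adjusted p = 0.607 with an estimated correlation), with Igfals (change 1.14, adjusted p = 0.00976) and F10 (change 0.23, adjusted p = 0.0348) past the test, and 5 higher and 1 lower adjusted over the list alone. Endothelial genes had a median of 0.111 (adjusted p = 0.0227, adjusted p = 0.607 with an estimated correlation) and no member past either test. All 3 lists lost their calls without the 4 mice with high Xist. The mean change went from 0.544 to 0.045 (adjusted p = 0.964) for CAR and PXR targets, from 0.122 to 0.055 (adjusted p = 0.249) for hepatocyte genes and from 0.108 to -0.061 (adjusted p = 0.245) for endothelial genes. The CAR and PXR score lay between 0.66 and 1.03 in the mice with high Xist and at -0.0017 and 0.097 in AspClo_60 and AspClo_62. With all 6 mice no list passed with an estimated correlation, and that test was not applied to these 2 mice alone. Another 14 lists, which had not passed in all 6 mice, passed in these 2 at the preset correlation. Means there were -0.702 for lipogenesis genes (adjusted p = 1.86e-09), -0.597 for macrophage genes (3.19e-08), -0.595 for cholesterol synthesis genes (2.8e-08), -0.493 for lipid-associated macrophage genes (0.00084), -0.353 for type I interferon genes (4.26e-05), -0.302 for antigen presentation genes (0.000214), -0.221 for fibrosis genes (0.00695) and -0.155 for cell cycle genes (0.000214). They were 0.39 for ER stress genes (adjusted p = 1.86e-09), 0.264 for PPAR-alpha targets (3.13e-08), 0.213 for bile acid genes (0.0268), 0.073 for exocrine pancreas genes (0.0498), -0.088 for T and NK cell genes (0.025) and -0.072 for T cell exhaustion genes (0.0131). Without the 4 arrays nearer the other group 6 lists that had not passed with them did so in the comparison of all 6 mice, with means of -0.189 for fibrosis genes (adjusted p = 0.000395), -0.225 for lipid-associated macrophage genes (0.00268), -0.145 for macrophage genes (0.0372), -0.067 for cell cycle genes (0.0358), -0.16 for p53 targets (0.0465) and 0.336 for Kupffer cell genes (0.0275). Those arrays were selected on the measured values, and without them the vehicle mean lies further from healthy. Falls of lists raised by the diet follow in part from that selection.

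In all, 335 genes passed, 168 higher and 167 lower, and 2492 had an unadjusted p under 0.05. The count was 140 without AspClo_61, 179 without AspClo_64, 123 without AspClo_58, 173 without AspClo_63 and 571 without AspClo_62. It was 7 without the 4 mice with high Xist, and 2 of those 7 genes were among the 335. Of the 34 named genes that passed, 26 kept their call without any 1 mouse. Adgrv1, Alas2, Cyp2b13, F10, Nipal1 and Tkt lost it without AspClo_61, Acot3 without AspClo_58 and Ugdh without AspClo_63, among others, with highest adjusted p between 0.0571 and 0.121. The CAR and PXR list lost its call without AspClo_58 (adjusted p = 0.184), the endothelial list without AspClo_61 (adjusted p = 0.123) and the red blood cell list without AspClo_60 (adjusted p = 0.0855), among others.

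The drug arms were also compared with each other, which asked where their effects differ and does not use the vehicle mean. The complement gene C6 averaged 10.48 ± 0.62 (SD, n = 10) under sulindac and 8.69 ± 0.92 (n = 6) under aspirin with clopidogrel, against 10.75 ± 0.47 (n = 5) in healthy livers (change -1.79, SE 0.331, adjusted p = 0.00759). Pnldc1, Serpina12 and Arsa were also lower under aspirin with clopidogrel, with changes of -1.50, -1.44 and -1.43. Nt5e was higher by 2.25 (SE 0.449, adjusted p = 0.0115), as were Sult2a2 (5.31), Cyp3a41a (4.27), Xist (4.13), Slc22a26 (3.83), Cyp3a16 (3.43), Acot3 (3.07), Nipal1 (2.40), Hao2 (2.31) and Prom1 (1.97). Cyp4a12a, Eif2s3y, Adgrv1, Nat8, Osbpl3 and Cyp2d9 had changes of -2.91, -2.74, -2.65, -2.37, -2.20 and -2.07. Adjusted p of these genes lay between 0.00182 and 0.0464. Fitm1 (-1.37, adjusted p = 0.00172), Aox1 (-0.60, adjusted p = 0.0339) and Gstp1 (-0.43, adjusted p = 0.00616) were lower than under sulindac too. In AspClo_60 and AspClo_62, with low Xist, C6 was at 9.67 and 9.85 and Arsa at 8.62 and 9.04. Nt5e was at 6.27 and 6.64 there and Aox1 at 10.22 and 10.28. For C6, Arsa, Nt5e and Aox1 these mice lay inside the range of the sulindac mice, and those with high Xist outside. Fitm1 and Gstp1 lay below that range in AspClo_60 (8.44 and 12.66) and inside it in AspClo_62 (9.67 and 12.88). Drug and sex cannot be told apart here with 2 such mice.

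Female-biased liver genes had a median of 1.61 in this comparison (adjusted p = 9.48e-24), the only list of the 5 main comparisons that passed with an estimated correlation (adjusted p = 0.0439). Of its 18 members 9 passed over all genes and 15 adjusted over the list alone. Its mean change was 1.92, and 0.06 (adjusted p = 0.855) without the 4 mice with high Xist. Higher lists were targets of CAR and PXR (median 0.185, adjusted p = 0.000118), hepatocyte genes (0.047, adjusted p = 0.000192) and ER stress genes (0.101, adjusted p = 0.0435). Lower lists were lipid droplet genes (-0.292, adjusted p = 1.58e-07), male-biased genes (-0.596, adjusted p = 3.75e-07), cell cycle genes (-0.092, adjusted p = 7.62e-05), NRF2 targets (-0.19, adjusted p = 0.000118), fibrosis genes (-0.138, adjusted p = 0.00258), lipid-associated macrophage genes (-0.242, adjusted p = 0.0254) and macrophage genes (-0.173, adjusted p = 0.0308). With an estimated correlation these 10 lists had adjusted p between 0.31 and 0.997. Without the 4 mice with high Xist the mean change of CAR and PXR targets went from 0.539 to 0.04 (adjusted p = 0.267) and that of hepatocyte genes from 0.104 to 0.036 (adjusted p = 0.577), and that of male-biased genes turned to 0.302 (adjusted p = 0.761). It went from -0.208 to -0.783 for macrophage genes (adjusted p = 1.32e-10), from -0.279 to -0.648 for lipid-associated macrophage genes (0.000119), from -0.11 to -0.231 for cell cycle genes (2.34e-07), from -0.203 to -0.311 for fibrosis genes (0.00194) and from 0.1 to 0.444 for ER stress genes (1.25e-10). Macrophage scores were -0.66 in AspClo_60 and -0.19 in AspClo_62, between 0.16 and 0.62 in the mice with high Xist and between -0.033 and 0.85 under sulindac, so the lower macrophage list rested on AspClo_60 and AspClo_62. Lipid-associated macrophage scores were -0.44 and -0.25 in these 2 mice, between 0.12 and 0.35 with high Xist and between -0.087 and 0.86 under sulindac. List tests without the mice with high Xist, which leave 2 mice, used the preset correlation only. Another 9 lists, which had not passed in all 6 mice, passed without the 4 mice with high Xist, with means of -0.813 for lipogenesis genes (adjusted p = 1.25e-10), -0.577 for cholesterol synthesis genes (1.15e-07), -0.462 for Kupffer cell genes (0.0151), -0.447 for oncofetal genes (0.0285), -0.373 for type I interferon genes (3.3e-05), -0.341 for acute phase genes (0.00891), -0.31 for antigen presentation genes (0.000426), -0.173 for endothelial genes (0.00135) and 0.375 for PPAR-alpha targets (1e-10).

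Adjusted over the list alone, 8 CAR and PXR targets were higher and 3 lower, 2 hepatocyte genes and 1 lipid droplet gene were higher, and 6 lipid droplet genes, 6 male-biased genes and 5 NRF2 targets were lower. Over all genes, 4 and 1 CAR and PXR targets, 1 hepatocyte gene and 1 lipid droplet gene, and 2 each of the lipid droplet, male-biased and NRF2 lists passed in those directions. No fibrosis, macrophage, cell cycle or ER stress gene passed. In all, 150 genes passed, 72 higher and 78 lower under aspirin with clopidogrel, and 1841 had an unadjusted p under 0.05. The count was 54 without AspClo_61, 77 without AspClo_64 or AspClo_58, 85 without AspClo_63 and 270 without AspClo_62. Without Sulin_20, Sulin_23, Sulin_25, Sulin_29 or Sulin_15 it was 74, 92, 84, 81 or 98. Without the 4 mice with high Xist it was 51, and 6 of those genes were among the 150. Of the 27 named genes that passed, 14 kept their call without any 1 mouse. Arsa, Cyp4a12a, Hao2, Igfals, Nipal1, Nt5e and Prom1 lost it without AspClo_61, Acot3, Adgrv1, Aox1, Osbpl3 and Serpina12 without AspClo_58, and Vldlr without AspClo_63, among others, with highest adjusted p between 0.0538 and 0.116. The macrophage list lost its call without AspClo_60 (adjusted p = 0.771), the ER stress list without AspClo_62 (adjusted p = 0.709) and the lipid-associated macrophage list without AspClo_60 (adjusted p = 0.212), among others.

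The drug targets did not pass in any comparison. Ptgs2 averaged between 4.30 and 4.38 in the 5 groups, near the lower end of the scale, with changes of 0.039 under sulindac (adjusted p = 0.715) and -0.036 under aspirin with clopidogrel (adjusted p = 0.694). P2ry12 had a change of 0.13 under aspirin with clopidogrel (adjusted p = 0.627). With all arrays, lists of platelet genes, prostanoid pathway genes, T and NK cell genes, T cell exhaustion genes and chemokines did not pass in any of the 5 main comparisons, nor did those of clock, TGF-beta, bile acid, oncofetal, B cell, dendritic cell, neutrophil, skeletal muscle and exocrine pancreas genes. Of these, the T and NK cell, chemokine, TGF-beta and oncofetal lists passed for the diet, at the preset correlation, without the 4 arrays nearer the other group. At the same correlation and without the 4 mice with high Xist, the T and NK cell, T cell exhaustion, bile acid and exocrine pancreas lists passed for aspirin with clopidogrel against vehicle. The oncofetal list passed against sulindac. Platelet genes had medians of 0.018 (adjusted p = 0.507) under sulindac and 0.025 (adjusted p = 0.68) under aspirin with clopidogrel. The skeletal muscle score was 2.43 in Sulin_17, while the next highest was 0.061 in Sulin_26.

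Both drug arms shared 16 genes past the test, all in the same direction, where independent lists would share 0.333 in the same direction. They were Wdfy1, Nnt, Plekhj1, Hba-a1, Hbb-b2, Srp54a, Srp54c, Elob, Prdx4, Yif1a and Slc39a12, with Slc25a37, Entpd4, Lonrf3, Cmtm4 and Paip1, and those outside the naming rule were chosen after their values were seen. AspClo_60 lay inside the range of the healthy and vehicle mice for Wdfy1, at 5.04. Nnt and Paip1, and Slc25a37 and Entpd4, lie within 5 gene positions of each other. The arms share the 9 vehicle mice, and the animal numbers of both arms lie apart from those of the healthy and vehicle mice. Simulated unchanged groups shared 0 genes, which decides nothing, since unchanged groups call few genes by construction. With the vehicle mice divided between the arms the mean was 4.34 shared genes (0 to 9 over 50 splits). Mean calls were then 30.4 for sulindac and 138 for aspirin with clopidogrel, against 34 and 335 with all 9. Fewer calls and fewer shared controls cannot be told apart as the reason for the lower number. The correlation of fold changes across genes was 0.439 observed, 0.459 in simulated unchanged groups and 0.22 with divided vehicle mice. The covariance was 0.0117 observed and 0.00531 simulated, a difference of 0.00641. Genes are not independent replicates.

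Kitl and Lad1, the genes that passed for the diet, did not pass under either drug. Kitl had changes of 0.083 under sulindac (adjusted p = 0.779) and -0.019 under aspirin with clopidogrel (adjusted p = 0.951), and Lad1 of -0.168 (adjusted p = 0.471) and -0.276 (adjusted p = 0.127). Across 17097 genes the split correlation of diet and drug effects was 0.277 for sulindac (SD over splits 0.053, range 0.207 to 0.437), on the side of movement further in the diet's direction. For aspirin with clopidogrel it was 0.145 (SD 0.0468, range 0.0875 to 0.265). The SD over splits is not a sampling error. Without dividing the vehicle mice the values were 0.0962 and 0.00599, against -0.436 and -0.379 in simulated unchanged groups. Covariance exceeded the simulated value by 0.00712 for sulindac and 0.0055 for aspirin with clopidogrel. Both correlations changed sign, to -0.0923 and -0.207, when the 4 arrays nearer the other group were left out. These arrays were picked by their place between the healthy and vehicle means. Leaving them out moves the vehicle mean away from healthy, which alone can lower the correlation. The change of sign therefore does not show movement toward healthy. Without the 4 mice with high Xist the value for aspirin with clopidogrel was -0.0671.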

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

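The tests on Xist except the one on the number of mice, the tests on Wdfy1 and its companions, and those on arrays nearer the other group were chosen after the results were seen. Single mice lay far from the rest of their group in 13 of 214 gene and group pairs (6.1%) and in 5 of 84 list and group pairs (6.0%), and chance alone gives about 1 in 20. In vehicle mouse Veh_high_1831 these were Abcd2 at 4.803 (next value 6.233), Entpd4 at 7.273 (6.938), Nat8f5 at 8.27 (6.783) and Paip1 at 9.081 (8.515). In Veh_high_798 they were Sult2a2 at 5.489 (4.357), Xist at 5.026 (4.68) and the NRF2 list at 0.2741 (-0.09831). In Veh_low_1819 they were Aox1 at 11.01 (10.68) and Cidea at 6.765 (9.457), in Veh_low_794 Nat8 at 9.596 (9.201) and the adipose list at 1.431 (0.276), and in Veh_low_1810 Gadd45a at 5.158 (5.792). In treated mice they were F10 at 11.47 in AspClo_62 (11.69), Vldlr at 5.612 (5.181) and the cell cycle list at 0.2535 (-0.02872) in AspClo_63, and Prom1 at 5.096 in Sulin_15 (4.739). In healthy mouse Hlth_1807 they were the cholangiocyte list at 0.6716 (-0.1125) and the stellate list at 0.3168 (-0.03543).

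Xist was high and Eif2s3y low in 4 of the 6 mice given aspirin with clopidogrel, and the 19 called genes of the sex lists kept a median of 0.0109 of their fold in the low-Xist mice AspClo_60 and AspClo_62. A total of 18 of these 19 genes had under 50% of their fold there, which argues against the treatment as their source, and females among males would give such values. The 19 include sex chromosome genes, and the mice were split on Xist, so part of this count was fixed by the split. Fewer mice are not the whole reason why 335 calls became 7, since pairs of high-Xist mice gave 181 to 396 calls (median 293), but the median of 27.5 over the 14 other pairs rests on these pairs, and pairs with 1 high-Xist mouse gave a median of 4.5, so for effects other than sex the loss through fewer mice stays open. Of the other 316 calls, 127 kept at least 0.75 of their fold in these 2 mice, where sex alone would leave folds near 0, and 110 kept under 0.5 (median ratio 0.636). Which of these genes follow treatment and which follow sex cannot be told apart gene by gene, because 2 mice are few and the calls were chosen with them included.

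A total of 9 genes separated the 10 sulindac mice from the 14 healthy and vehicle mice, against at most 1 in 99 other splits. Wdfy1, Nnt, Plekhj1, Entpd4 and Slc25a37, examined here, were 5 of them, and Aplp2, Hba-a1, Il13ra1 and Sft2d1 the others. Of the 5 examined, 0 genes had a sulindac mouse inside the untreated range. A genetic background that differs between cohorts may underlie this, since C57BL/6J mice carry a deletion in Nnt. Also, 2 pairs of called genes (Nnt with Paip1, Slc25a37 with Entpd4) lie within 5 gene positions, against 0.306 in random sets (349 of 10000 had as many). Such pairs were also in excess for aspirin with clopidogrel against vehicle (43 against 31.7, 307 of 10000) and between the drug arms (14 against 6.29, 52 of 10000). For HCC there were 0 against 0.0584. Neighbouring calls therefore do not single out a background. In the aspirin and clopidogrel arm 4 of the 5 genes had a mouse inside the untreated range, AspClo_60 for Wdfy1 at 5.04 among them. This argues against a treatment effect that moves every mouse of that arm out of the range. AspClo_60 lay inside that range for Nnt too (9.70) but beyond it for Entpd4 (5.93) and Slc25a37 (8.105). AspClo_63 lay inside it for Entpd4 (6.72) but beyond it for Nnt (10.66). These opposite orders argue against an effect that differs between mice only in its overall strength. An effect that varies by mouse and by gene would give them, so treatment and background stay open in that arm. In the sulindac mice treatment and background cannot be told apart, because the labels give no cohort and a cohort difference would coincide with treatment. No genotype was measured.

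Healthy mice Hlth_1798 and Hlth_1807 and vehicle mice Veh_low_794 and Veh_low_1819 lay nearer the other group, with placements of -0.542, -0.411, 0.279 and 0.347. On 123 lipid and sterol genes 4 of the 4 lay on the other group's side (-0.624, -0.449, 0.226 and 0.458) and 10 of the 10 other arrays on their own. The 4 were selected over the brighter genes, which overlap these, so neither this nor the counts without the 4 are separate evidence. Over 39 lists Hlth_1798 and Hlth_1807 lay outside the range of the other 7 vehicle mice in 21 and 19 lists, where each of those 7 lay outside the range of the remaining 6 in 3 to 18. Among lists picked after their values were seen, Hlth_1807 lay beyond all 9 vehicle mice for fibrosis genes (score 1.04 against at most 0.30), cholangiocyte genes (0.67 against -0.088) and Kupffer cell genes (-0.92 against at least -0.59). Hlth_1798 did so for macrophage genes (1.35 against at most 0.77) and NRF2 targets (1.05 against 0.27). Because they were picked for lying outside, these lists cannot weigh for or against an exchange. Mice or samples exchanged between the groups, inflamed healthy livers and unaffected vehicle livers with the diet as labelled (mean placement 0.439 toward the other group on the lipid and sterol genes), and disease that varies between mice cannot be told apart with 4 arrays picked this way.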

How the results depend on the processing

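The tests without high-Xist mice, with Xist as a covariate and without the 4 arrays nearer the other group were chosen after the results were seen. For counts that moved by over 1.5 times the cause was not tested, except that fewer mice, fewer genes or a stricter threshold lower or raise counts by construction. With array weights the counts were 375 for the diet (2 in the report), 206 for sulindac (34), 613 for aspirin with clopidogrel (335), 407 between the drug arms (150), 668 for HCC against healthy (17) and 12 for vehicle without HCC against healthy (0). With only the groups compared in the fit, limma gave 0 for the diet (917 at unadjusted p under 0.05), 0 for HCC (1536), 91, 111, 239 and 1 in the order sulindac, aspirin with clopidogrel, drug arms, HCC against healthy. At 2-fold or more the counts were 0 for the diet, 5 for HCC, 5, 56, 36 and 7. Each probe set on its own gave 1 for the diet, 74 for sulindac, 568 for aspirin with clopidogrel and 11 for HCC against healthy, and the mean of probe sets gave 5 for the diet. Without dim genes the counts were 82 for sulindac and 35 for HCC against healthy, and with cyclic loess 60 and 28. Against vehicle without HCC alone sulindac gave 168, against vehicle with HCC alone 8, and aspirin with clopidogrel 157. Without Veh_low_794 and Veh_high_798 the diet gave 1.

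Without the 4 arrays nearer the other group the counts were 959 for the diet (2 shared with the report), 143 for sulindac (31 shared), 819 for aspirin with clopidogrel (307 shared), 856 for HCC against healthy (17 shared) and 505 for vehicle without HCC against healthy, and 19 diet lists passed (7 shared). The split correlations became -0.0923 for sulindac and -0.207 for aspirin with clopidogrel, a direction that the selection of these arrays favours. Over genes called for the diet in the same part of the vehicle mice they were 0.708 and 0.696, from the 14 of 100 splits with at least 10 such genes (at most 31). These splits were picked by the diet calls in 1 part, which favours parts far from healthy and leaves nearer arrays as the drug reference. That selection alone can raise the correlation, so no conclusion on movement is drawn from these 2 values. Without high-Xist mice aspirin with clopidogrel gave 7 genes (2 shared), 17 lists (3 shared) and a split correlation of -0.0671, and the drug arms 51 genes (6 shared). With Xist as a covariate these gene counts were 8 (2 shared) and 60 (9 shared). Both changes turned Sult2a2 to -0.03859, Xist to -0.04631, Cyp3a41a to -0.1158, Cyp3a16 to -0.06915, Nipal1 to -0.08253, Cyp3a44 to -0.04191, Eif2s3y to 0.3314, Cyp2d9 to 0.1236 and Alas2 to 0.02461 against vehicle, and Xist to -0.1233, Cyp3a16 to -0.01718 and Eif2s3y to 0.1433 against sulindac. Without high-Xist mice the male-biased list turned to 0.444 and 0.302 and the endothelial list to -0.0606, and the female-biased, CAR and PXR and hepatocyte lists lost their calls in both comparisons. The cholangiocyte list of the diet turned to 0.0262 without Hlth_1807 (-0.195 to 0.0262 over single mice) and to 0.0465 without the 4 arrays. These list values are mean log2 changes. Without the 4 arrays 23 of 35 called lists kept their call and 12 lost it, the cholangiocyte list among them.

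With an estimated correlation camera passed 0 lists for the diet, HCC, sulindac and aspirin with clopidogrel and 1 between the drug arms, against 11, 9, 7, 8 and 11 at the preset one. Without dim genes 37 of the 46 called lists kept their call, 8 of 11 for the diet and 4 of 7 for sulindac among them. Those of cholangiocyte genes and p53 targets for the diet, fibrosis for HCC, cell cycle and Kupffer cell genes for sulindac, and CAR and PXR targets and red blood cell genes for aspirin with clopidogrel lost it, and the adipose list, called for the diet and sulindac, gave no value. Without members of more than 1 list 38 kept their call, and 8 lost it: adipose genes, aryl hydrocarbon receptor and p53 targets for the diet, acute phase and fibrosis genes for HCC, cell cycle genes for sulindac, CAR and PXR targets for aspirin with clopidogrel, and ER stress genes between the drug arms. Fry passed 0, 0, 1, 3 and 1, and the exact permutation of mice 0, 0, 1, 6 and 3. Leaving out each mouse in turn gave 1 to 36 genes for the diet, 0 to 33 for HCC, 19 to 148 for sulindac, 123 to 571 for aspirin with clopidogrel, 54 to 270 between the drug arms, 0 to 1 for vehicle without HCC and 1 to 110 for vehicle with HCC against healthy. List counts ranged from 10 to 17, 6 to 11, 5 to 10, 5 to 16 and 9 to 12 for the main comparisons in order. Of called named genes 53 of 94, and of called lists 23 of 46, passed without every single mouse. Centring arrays on their median kept 104 of 104 named gene results, cyclic loess 102, and the trend with robust prior 100. Genes near the lower end of the scale, Ptgs2 among them, have compressed changes because background adds to their signal. No paired analysis was possible because the labels share no replicate numbers between groups.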

Other observations

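The test of chance by regrouping was fixed before the data were examined, and the clock tests and the choice of genes in the next paragraph were made after the results were seen. Among genes with the Xist difference set aside, Cidea had a log2 change of -3.67 in all 6 mice given aspirin with clopidogrel, -2.97 in the 2 low-Xist mice and -4.01 in the 4 high-Xist mice. Pparg had changes of -1.13, -1.12 and -1.13, Osbpl3 of -2.32, -2.19 and -2.38, and Socs2, outside the naming rule, of 1.63, 1.88 and 1.51. Hba-a1 had changes of 1.21, 1.07 and 1.27. Fitm1 differed more, at -1.70, -0.81 and -2.15. The lipid droplet list kept its call in the low-Xist mice, at a mean log2 change of -0.59 (camera adjusted p = 1.78e-05 at the preset correlation), while in all 6 mice it had adjusted p = 0.129 with an estimated correlation. The 2 mice differed, with list scores of -0.56 in AspClo_60 and 0.062 in AspClo_62, against a vehicle mean of 0.339. Vehicle scores were -0.48 and -0.14 in Veh_low_1819 and Veh_low_794, 2 of the arrays nearer the other group, and between 0.36 and 0.85 in the other 7 mice. Cidea was at 4.86 and 7.98 and Pparg at 6.23 and 6.44 in the 2 mice, while the lowest vehicle values were 6.77 for Cidea, in Veh_low_1819 (9.04 in the other 8), and 6.64 for Pparg. Whether lipid droplet genes fall with this treatment apart from sex stays open, since only 2 mice bear on it and Cidea (adjusted p = 0.45) and Pparg (adjusted p = 0.129) did not pass there.

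Cry1 fell with HCC and under sulindac, and it is a clock gene. A score of 9 day genes minus 4 night genes, without Cry1, averaged 0.084 ± 1.18 (SD, n = 5) in healthy mice, -0.99 ± 0.67 (n = 5) without HCC, 0.59 ± 2.36 (n = 4) with HCC, 1.41 ± 1.15 (n = 10) under sulindac and 0.78 ± 1.13 (n = 6) under aspirin with clopidogrel. Between sulindac and vehicle the difference was 1.70 (exact permutation p = 0.0238, adjusted p = 0.0952 over 4 comparisons), with 8 of 9 day genes higher and 4 of 4 night genes lower, which is consistent with a shifted clock phase before adjustment. Under aspirin with clopidogrel 8 of 9 and 4 of 4 genes had these directions too, with a difference of 1.07 (exact permutation p = 0.206) and a Cry1 change of -1.06 (adjusted p = 0.0609), against the same 9 vehicle mice. Between the vehicle groups the difference was 1.58 (exact permutation p = 0.254, 7 of 9 and 4 of 4 genes), where a clock phase and an effect of HCC on Cry1 cannot be told apart with 9 mice. Collection times are not given in the sources used here, and an effect of drug or feeding on the clock stays open. Dbp, chosen after its values were seen, averaged 8.87 ± 1.48 (n = 10) under sulindac and 5.41 ± 0.72 (n = 5) in healthy livers, and it lay between 5.31 and 10.20 under aspirin with clopidogrel. In vehicle mice it lay between 4.40 and 5.20 without HCC and was 4.60, 4.37, 10.00 and 10.20 in Veh_high_798, Veh_high_1770, Veh_high_1831 and Veh_high_2088. The last 2 are the mice without which none of the named HCC genes kept its call, and the count also fell, to 2, 4 and 4, without Veh_low_2091, Veh_low_794 or Veh_low_1819, where Dbp was 4.90, 4.40 and 4.88. Cry1 was also below the range of the mice without HCC in Veh_high_798 and Veh_high_1770, at 6.76 and 6.35, where Dbp was low.

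Regrouping the compared mice in 100 splits, the real one included, gave the counts that chance alone can reach. Only the real split gave as many genes for sulindac (1 split, 34 against 3 in the highest other) and the drug arms (1 split, 150 against 21), so chance is an unlikely source. For HCC (2 splits, 15 against 30) and aspirin with clopidogrel (2 splits, 335 against 507) few splits gave as many. Both numbers of splits lay below the limit for chance that was set beforehand. In both, however, another grouping called more genes than the real one, so chance is not taken as excluded there. The split with 507 grouped the 4 high-Xist mice with vehicle mice Veh_high_1831 and Veh_high_2088. Chance cannot be excluded for the diet (8 splits, 2 against 37) or for HCC against healthy (12 splits, 17 against 604). For vehicle without HCC against healthy limma gave 0 genes (909 at unadjusted p under 0.05, 414 called in the highest other split). All 100 splits reach a count of 0, so the test cannot decide there. The splits with 604 and 414 genes grouped Hlth_1798 and Hlth_1807 with vehicle mice, which points to a structure of the arrays. The split with 37 grouped Hlth_1798 with 4 vehicle mice and left Hlth_1807 with the other healthy mice.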
